A study of Mus musculus with 3 samples.

How the data were processed

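Chromatin-fraction RNA of lipid A-treated mouse macrophages was measured in 3 libraries of 1 group, with replicate numbers, dose, time and amount of starting RNA taken from the labels. For each library the authors deposited 3 tables made on build mm10 with GENCODE M21, per the deposited file notes. The gene table and the first transcript table hold expected counts and TPM, per the file headers, together with posterior mean TPM, its credible bounds and, for transcripts, the percent of the gene's abundance. The second transcript table holds estimated counts and TPM from a separate quantification of the reads, per the file headers. The column layouts are those of RSEM and kallisto, but the tools, their versions and the strand setting are not given in the sources used here. TPM is scaled by the authors to a fixed total with effective lengths, so it sums to the same total in each library and carries no depth. Expected counts are not normalised. Because the strand setting is unknown, reads of overlapping genes on opposite strands, such as Xist and Tsix, are uncertain.

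All 55536 mouse gene identifiers in the gene tables matched GENCODE M21, which gave symbols, coordinates and biotypes. The tables also list 26248 entries with bare numbers as names, 96 spike-in controls and the phiX genome, and these were kept out of library sizes and tests. The phiX row held 1.03%, 0.24% and 0.22% of expected counts in libraries 1 to 3. Library totals on annotated genes were 16301150, 17033725 and 16205704 expected counts, so that 3 counts, the most that a count of 0 allows at 95% confidence, equal 0.18, 0.18 and 0.19 CPM. Intervals and limits of this kind cover counting error only.

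Gene lists, named genes, tests and most alternatives were fixed before the data were examined. The 22 lists cover response genes, macrophage genes, markers of 8 other cell types, dividing cells and RNA classes. Genes named were the 4 members of each list with the highest mean TPM and up to 2 undetected members, 15 genes chosen by name, the 10 genes with the highest mean TPM, up to 10 genes with the widest range among those past the spread test, and 5 protein-coding genes with a noncoding main transcript. No gene passed the spread test, so that part named none. For Rmrp, Aldoa and Ddit3, which have 2 gene identifiers each, the entries were summed in list levels. In list deviations each detected identifier entered on its own, so Rmrp counted as 2 entries there. A gene was called detected at a mean expected count of at least 10. List levels are medians of log2(TPM + 0.1) per library, given as mean ± SD over libraries, with percentiles among 10000 random lists matched on merged exon length in 10 bins. Contrasts are differences of list medians within a library, tested by an exact two-sided sign-flip permutation over libraries, whose smallest p with 3 libraries is 0.25. The test therefore cannot pass 0.05.

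The spread between libraries was tested with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM scaling, filterByExpr, an intercept-only quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. The gene's deviance over its degrees of freedom was set against the trended prior as an F ratio. On simulated counts with 200 genes changed in 1 library, 12974 genes tested, it recovered 43 of 100 genes changed 4-fold and 85 of 100 changed 8-fold, with 0 unchanged genes called. Each simulated gene had the dispersion of the trend, without scatter around it, and changed genes were drawn above a minimum abundance. Recovery in the real data may therefore be lower. List deviations used log2 CPM with TMM scaling and a prior count of 0.5, for lists with at least 5 detected members, against 10000 random lists matched in 20 expression bins. On simulated values for 14396 genes, 10 of 10 lists raised by 0.5 in log2 in library 1 fell outside the 2.5 and 97.5 percentiles there, and 1 unchanged list did. The simulated noise was independent between genes, so this does not cover lists whose members vary together. The replicates share 1 donor record in the labels, so whether they came from separate mice is not given, and spreads describe these libraries.

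Alternatives were pseudocounts of 1 and 0.01, the second quantification, posterior mean TPM, TPM rescaled without mitochondrial genes and the 10 genes with the most reads, detected members only, means in place of medians, CPM without length correction, DESeq2 1.42.0 size factors and dispersion outliers, no filter, robust empirical Bayes, a TPM minimum of 10 and leaving out each replicate. TPM rescaled over genes of at least 300 nt was added after seeing the data. Further work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0.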

Results

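RNA bound to chromatin was sequenced from mouse bone-marrow-derived macrophages, primary phagocytes grown from marrow precursors of C57BL/6J mice. The cells had been exposed for 30 min to 100 ng/ml lipid A, the part of bacterial endotoxin that activates the receptor TLR4. Ribosomal RNA was depleted, and the remaining RNA was sequenced as total RNA, so that unspliced and non-polyadenylated transcripts were kept. The chromatin fraction holds nascent transcripts together with RNAs that stay in the nucleus. There was 1 group of 3 libraries, which the labels number as biological replicates of the same donor record. Library 1 was made from 1 µg of RNA, library 2 from 250 ng and library 3 from 500 ng. The libraries held 16301150, 17033725 and 16205704 expected counts on annotated genes. No unstimulated library was analysed here, so levels and contrasts within libraries are given, not induction. Each amount of starting RNA occurred in 1 library and cannot be told apart from other replicate differences. Coordinates are those of mouse build mm10.

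Noncoding RNAs held a large part of the reads. The 10 genes with the most reads took 33.6% ± 1.15 (SD, n = 3) of expected counts, and long intergenic noncoding RNAs as a class took 30.8% ± 0.96. Of that class, 14.7% ± 3.21 of expected counts remained without the gene models Gm26917 and Gm42418, which are described below. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) is a noncoding RNA of nuclear speckles, and it held 8.61% ± 2.17 of expected counts at 16550 ± 12252 TPM, a measure of transcript abundance corrected for length and scaled to a fixed library total. Its TPM was 8185, 10853 and 30613 in libraries 1 to 3, and the mean without library 3 was 9519. In log2 CPM, normalised counts without length correction, it had 16.26, 16.22 and 16.62. Neat1 (ENSMUSG00000092274.3, chromosome 19, 5824708 to 5845478) builds nuclear paraspeckles. It held 3.96% ± 1.11 of expected counts at 2209 ± 1049 TPM. Xist, the noncoding RNA that coats the inactive X chromosome, held 1.35% ± 0.11. The gene model with the most reads was Gm26917 on chromosome 17 (39843013 to 39846341), with 14.5% ± 2.72 of expected counts. It lies beside the models Gm42418 and CT010467.1, the last of which is annotated as ribosomal RNA, and the 3 together held 17.3% ± 3.50. Reads of these neighbouring models can be shared with ribosomal RNA repeats. Their split is therefore uncertain, as is whether they are long intergenic RNA or ribosomal RNA left after depletion. Ahnak was the protein-coding gene with the most reads, at 0.89% ± 0.21 of expected counts.

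In all, 14396 genes had a mean expected count of at least 10, of which 10983 were among the 22028 annotated protein-coding genes, 409 were long intergenic noncoding RNAs and 64 were small nucleolar RNAs. Per library, 14211, 14170 and 14695 genes reached that count. Protein-coding genes took 62.1% ± 0.51 of expected counts but 19.3% ± 5.23 of TPM. Small nucleolar RNAs took 0.54% ± 0.29 of expected counts but 48.2% ± 11.5 of TPM, which divides counts by effective length. In the TPM of a second quantification, also deposited, the small nucleolar share was 10.4% ± 5.16, but microRNA genes took 26.6% ± 11.9 against 0.018% ± 0.003 in the first. Genes under 300 nt together held 65.3% ± 8.13 of TPM in the first quantification and 50.2% ± 10.1 in the second. In the first quantification the genes with the highest TPM were mostly small RNAs: Gm26447 at 93656 ± 23125 TPM, Snord22 at 84560 ± 27417, Gm22988 at 73442 ± 5104, Snord15b at 48984 ± 12306 and Gm25835 at 31218 ± 7966. The others among the 10 highest were 2 overlapping entries of Rmrp (55445 ± 12653 and 17291 ± 10364 TPM, the latter 11458 without library 2), Gm26917 (35147 ± 5463), CT010467.1 (16916 ± 8351) and Malat1. This order did not hold in the second quantification, where Gm26447 had 7944 ± 5348 TPM, Snord22 6507 ± 4165 and Gm22988 10342 ± 5859, below Gm26917 at 46944 ± 1837 and CT010467.1 at 36454 ± 5309. Malat1 had 15208 ± 8803 TPM there, above the 3 small RNAs by the mean but below each of them in library 1, at 11066 against 14027, 11205 and 17106. The mean of Malat1 without library 3 was 9519 TPM in the first quantification. The small nucleolar share of TPM was 35.6% in library 3, against 58.2% in library 1 and 50.8% in library 2, and the median detected gene lay 0.52 above its own mean log2 TPM in library 3, with −0.37 and −0.14 in libraries 1 and 2. Deviations of gene lists between libraries are therefore given below on the scale of normalised counts, and TPM values of single libraries and means without a library carry this shift.

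Some NF-kB primary response genes were among the most abundant protein-coding transcripts on chromatin. All 28 members of the list were detected, 15 of them at a mean of at least 100 TPM, and the median member stood at 120.1 ± 48.1 TPM. Tnfaip2 (ENSMUSG00000021281.15, chromosome 12, 111442469 to 111455018) had the highest mean TPM of all protein-coding genes, at 1532 ± 434, but Ifrd1, which is outside the list, was above it in library 2 (1155 against 1119 TPM) and in library 3 (2139 against 1985). Tnfaip2 was followed within the list by the transcription factor gene Irf1 at 744 ± 193 TPM, the superoxide dismutase gene Sod2 at 613 ± 187 and Tnfaip3, which encodes the NF-kB inhibitor A20, at 535 ± 141. The chemokine gene Cxcl2 (ENSMUSG00000058427.10, chromosome 5, 90903871 to 90905938) had 470 ± 162 TPM. Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647), which encodes the inhibitor IkB-alpha, had 405 ± 171 TPM. The cytokine gene Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) had 274 ± 132 TPM.

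Immediate-early genes, the transcription factor and feedback genes that respond within minutes, had a median of 93.2 TPM over the 3 libraries, which was 50.7 without library 3. Of 28 members, 27 were detected and 13 had a mean of at least 100 TPM, or 9 without library 3. The highest were the phosphatase gene Dusp1 at 300.2 ± 122 TPM, the survival gene Mcl1 at 285 ± 176, Ppp1r15a at 271 ± 228 and the transcription factor gene Klf6 at 233 ± 106. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) had 127 ± 95.6 TPM and Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) had 120.2 ± 92.7 TPM. Ppp1r15a had 184, 99.8 and 531 TPM in libraries 1 to 3. Without library 3, in which TPM was higher for the median detected gene too, the means were 142 TPM for Ppp1r15a, 184 for Mcl1, 76.0 for Fos and 66.7 for Egr1. In log2 CPM the libraries lay closer, with 9.59, 8.51 and 9.90 for Ppp1r15a, 10.10, 9.67 and 10.45 for Mcl1, 6.35, 7.42 and 7.93 for Fos and 8.46, 8.16 and 9.24 for Egr1. Fosl1 was the undetected member, with 0 expected counts in each library. A count of 0 allows up to 3 counts, which is 0.18, 0.18 and 0.19 CPM (counts scaled to library size) in libraries 1 to 3.

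Genes usually described as induced hours after endotoxin were low. Of 18 members, 10 were detected, and the median member stood at 0.39 ± 0.17 TPM. The exceptions were Il10, the gene of an anti-inflammatory cytokine, at 45.1 ± 35.5 TPM, and Acod1, which encodes the enzyme that makes itaconate, at 20.6 ± 9.11. Il10 had 24.0, 25.3 and 86.1 TPM in libraries 1 to 3, with a mean of 24.7 without library 3, and in library 1 it lay below Acod1 at 30.1. In log2 CPM Il10 had 5.53, 5.35 and 6.38. Ebi3 followed at 7.32 ± 4.18 TPM, and Il12b (ENSMUSG00000004296.14, chromosome 11) at 2.06 ± 1.54, or 1.295 without library 1. Il6 (ENSMUSG00000025746.11, chromosome 5) had 0.51 ± 0.33 TPM from 21, 11 and 22 expected counts, and 0.33 TPM without library 3. Nos2, which encodes inducible nitric oxide synthase, had 4, 2 and 6 expected counts and was 1 of the 8 undetected members, with Csf2 another. The NF-kB list exceeded this list by 7.98 ± 0.59 (SD, n = 3) on the log2(TPM + 0.1) scale, and the immediate-early list exceeded it by 7.41 ± 1.18. Both differences were positive in 3 of 3 libraries. An exact two-sided sign-flip permutation test gave p = 0.25 for each, the smallest p that 3 libraries allow. In the second quantification the late list was higher, at 0.67 in log2(TPM + 0.1) against −1.15 in the first. The NF-kB list was higher there too, at 8.01 against 6.83.

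Interferon-stimulated genes lay between these extremes. Of 26 members, 24 were detected at a median of 19.2 ± 7.04 TPM. The highest were the guanylate-binding protein gene Gbp5 at 115 ± 61.3 TPM, Oasl2 at 86.4 ± 34.1, the antiviral gene Oas2 at 80.5 ± 20.3 and the signalling gene Stat2 at 77.2 ± 16.9. Ifit1 (ENSMUSG00000034459.8, chromosome 19) had 3.50 ± 1.46 TPM. Ifnb1, the gene of interferon-beta (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774), had 13, 1 and 1 expected counts and was undetected by the mean, as was Cxcl9. The NF-kB list exceeded the interferon list by 2.65 ± 0.40 in log2, again in 3 of 3 libraries. It exceeded the list of receptor, adaptor and kinase genes of the TLR4 pathway by 2.84 ± 0.51 in 3 of 3 libraries. For both contrasts the exact sign-flip p was 0.25. All 27 TLR4 pathway members were detected, at a median of 16.3 ± 4.87 TPM. The co-receptor gene Cd14 had 183 ± 65.5 TPM, Tbk1 93.8 ± 15.7, Irf3 88.4 ± 25.7 and Irak2 86.5 ± 10.1. The receptor gene Tlr4 itself (ENSMUSG00000039005.13, chromosome 4) had 6.99 ± 3.43 TPM.

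**Figure D1:**
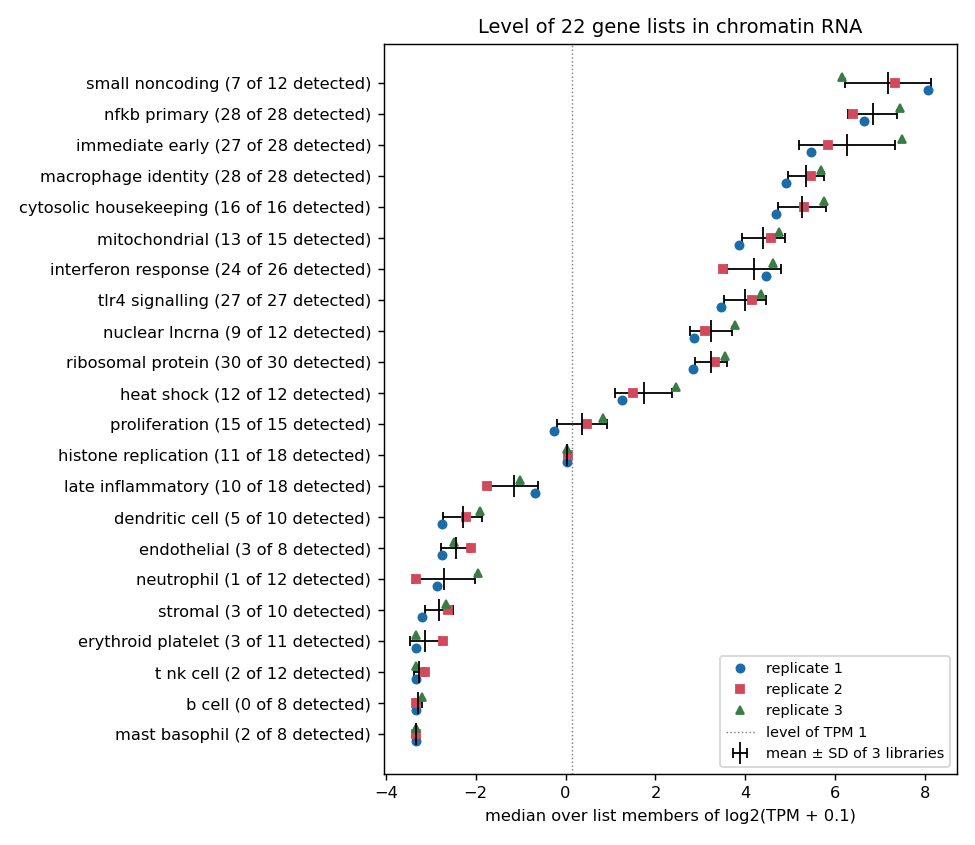
Each row is a gene list fixed before the data were examined, and the horizontal axis is the median over its members of log2(TPM + 0.1). Points are the 3 libraries, bars the mean ± SD, and the dotted line the level of TPM 1. The NF-kB list averaged 6.83 and the late inflammatory list −1.15, while the 8 lists of other cell types lay between −3.32 and −2.29.

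Genes of the macrophage lineage were all detected, 28 of 28, at a median of 42.3 ± 11.4 TPM. The inhibitory receptor gene Sirpa had 673 ± 84.5 TPM, the lysosomal protease gene Ctsb 276 ± 46.2, the NADPH oxidase gene Cybb 209 ± 84.5 and Csf1r, the receptor gene for the macrophage growth factor, 202 ± 46.5. Adgre1, which encodes the surface marker F4/80, had 74.6 ± 6.59 TPM. Against the median of the 8 lists of other cell types, the macrophage list was higher by 8.39 ± 0.23 in log2(TPM + 0.1), in 3 of 3 libraries, with an exact sign-flip p of 0.25. The size of this contrast depends on the pseudocount, since most markers of other cells had TPM near 0: it was 5.35 with a pseudocount of 1. For T and NK cells 2 of 12 markers were detected, Cd5 at 5.52 ± 3.06 TPM and Cd4 at 4.33 ± 1.97, and Zap70 at 0.22 ± 0.05 and Lck at 0.06 ± 0.08 were not. None of 8 B-cell markers was detected by expected counts, with Cd79a at 0.06 ± 0.04 TPM, Jchain at 0.04 ± 0.05, Ebf1 at 0.02 ± 0.03 and Ms4a1 at 0.01 ± 0.01. The B-cell list held 3.05e-05% of expected counts but 0.0012% of the counts of the second quantification. Of 12 neutrophil markers Mmp8 was detected, at 0.25 ± 0.12 TPM, while Ngp at 0.42 ± 0.30, Ltf at 0.29 ± 0.25 and S100a9 at 0.12 ± 0.11 were not. Dendritic-cell markers were detected in 5 of 10 cases, with Batf3 at 2.00 ± 1.01 TPM, Kmo at 0.85 ± 0.64, Zbtb46 at 0.62 ± 0.32 and Clec9a at 0.43 ± 0.22. Flt3 and Siglech were undetected by expected counts. The dendritic-cell list held 0.00089% of expected counts and 0.0022% of the counts of the second quantification. Of 8 mast-cell and basophil markers 2 were detected, Kit at 0.49 ± 0.25 TPM and Hdc at 0.19 ± 0.20, but not Cpa3 or Gata2. Of 10 stromal markers 3 were detected, Col3a1 at 0.24 ± 0.25, Col1a2 at 0.23 ± 0.18 and Col1a1 at 0.19 ± 0.17, while Postn stood at 0.10 ± 0.03. Of 8 endothelial markers, Vwf (ENSMUSG00000001930.17, chromosome 6, 125546774 to 125686679) reached 45.6 ± 9.95 TPM, against 1.18 ± 0.42 for Kdr, 0.48 ± 0.23 for Pecam1 and 0.16 ± 0.21 for the undetected Cdh5. Of 11 erythroid and platelet markers, Gp9 at 4.42 ± 2.41 TPM, Alas2 at 4.07 ± 1.20 and Itga2b at 1.93 ± 0.10 were detected, and Hba-a2 at 0.29 ± 0.12 was not. Some of these low values rested on 1 library. Kmo stood at 0.49 TPM and Hdc at 0.08 without library 3, Col1a1 at 0.115 without library 3, and Col3a1 at 0.11 without library 2. Among undetected markers, Cdh5 stood at 0.04 TPM without library 2, Lck and Jchain at 0.015 without library 1, and Ngp at 0.255, S100a9 at 0.075 and Ebf1 and Ms4a1 at 0.005 without library 3. The number of neutrophil markers detected was 2 without library 1 and 0 without library 2, and that of mast-cell and basophil markers was 1 without library 3. Detection and TPM in this paragraph are those of the first quantification. In the second, each list of other cell types but the endothelial one held a larger share of counts, so undetected markers are uncertain.

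**Figure D2:**
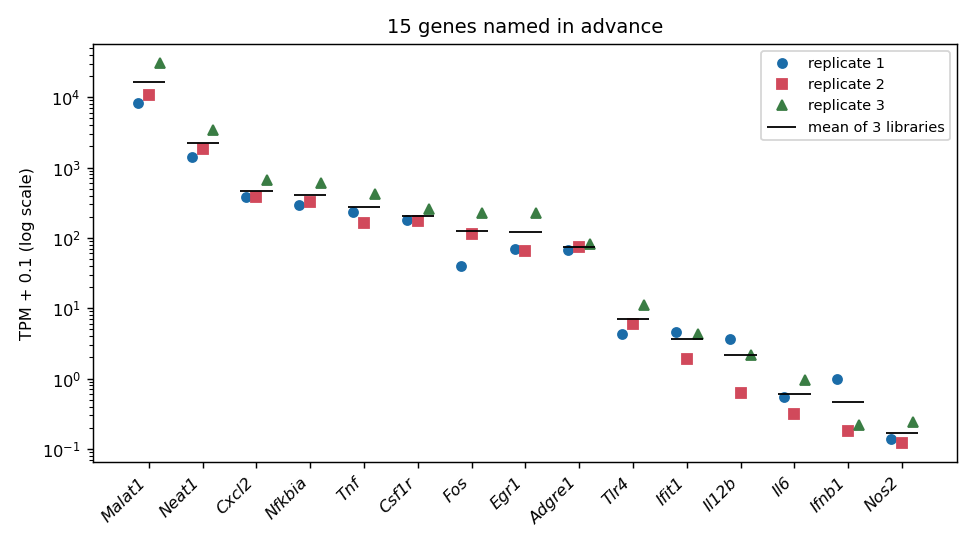
TPM + 0.1 on a log axis for the 15 genes chosen by name in advance, 1 point per library and a bar at the mean of 3 libraries. Malat1 averaged 16550 TPM (9519 without library 3), Cxcl2 470 TPM and Nos2 0.07 TPM (0.03 without library 3).

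Nuclear noncoding RNAs and ribosomal protein mRNAs had like medians and unlike shares of reads. The nuclear long noncoding RNA list had 9 of 12 members detected and a median of 10.2 ± 3.42 TPM, carried at the top by Malat1, Neat1, Xist (1007 ± 209 TPM) and Firre (119 ± 24.4), with Meg3 and Miat undetected. Its difference from the ribosomal protein list was 0.00 ± 0.23 in log2, positive in 2 of 3 libraries, with an exact sign-flip p of 1. It was 1.19 with detected members only and 1.502 without length correction. By share of reads they were far apart, with 14.1% ± 3.20 of expected counts for the 12 nuclear RNAs and 0.036% ± 0.004 for 30 ribosomal protein mRNAs. Ribosomal protein mRNAs had a median of 9.54 ± 2.25 TPM, and the highest were Rpl10 at 88.8 ± 21.8, Rps9 at 35.6 ± 8.66, Rpl23 at 27.8 ± 6.05 and Rpl27 at 23.6 ± 11.0. Cytosolic housekeeping mRNAs had a median of 40.0 ± 14.1 TPM, led by Eef1a1 at 469 ± 87.8, Fth1 at 400.4 ± 137, Ftl1 at 312 ± 60.2 and Actb at 160.5 ± 48.2. Mitochondrial genes took 0.064% ± 0.030 of expected counts. Their median lay 1.16 ± 0.13 above that of ribosomal proteins in log2, in 3 of 3 libraries, with an exact sign-flip p of 0.25, but the difference was 0.13 when means over members were used. The highest were mt-Co1 at 201 ± 83.8 TPM, mt-Atp8 at 97.3 ± 24.7, mt-Nd6 at 45.4 ± 11.0 and mt-Nd1 at 30.9 ± 5.37, while mt-Co2 and mt-Nd3 were listed at 0. Both have annotated near-identical nuclear copies, so their values are uncertain.

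Among small structured RNAs, 7 of 12 were detected, with Rmrp at 72736 ± 16364 TPM summed over its 2 entries, Rn7s1 and Rn7s2 at 13128 ± 2574 each and Rn7sk at 6635 ± 3700, and Rny1 and Rny3 undetected. Rn7s1 and Rn7s2 had equal values in each library, and their split is uncertain. All 15 genes of dividing cells were detected at a median of 1.24 ± 0.48 TPM, led by Mki67 at 43.0 ± 13.5, Tk1 at 31.8 ± 13.2, Pcna at 17.3 ± 7.09 and Top2a at 4.54 ± 1.53. Replication-dependent histone genes had a median of 0.92 ± 0.01 TPM with 11 of 18 detected. Their highest members were Hist2h2ac at 8.43 ± 2.73, Hist1h4c at 2.46 ± 0.28, the undetected Hist1h4b at 2.30 ± 0.28 and Hist2h3b at 1.97 ± 0.50. Histone genes have similar copies, and their values are uncertain. All 12 heat shock genes were detected at a median of 3.69 ± 1.73 TPM, led by Hspa8 at 122 ± 52.8, Hspa5 at 85.2 ± 31.2, Dnaja1 at 42.6 ± 33.2 (23.5 without library 3) and Hsp90aa1 at 22.4 ± 10.5.

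Set against 10000 random lists of equal size matched on gene length, the medians of the NF-kB, immediate-early, interferon, macrophage and TLR4 lists lay above every random list. The late inflammatory list lay at percentile 97.8, genes of dividing cells at 67.9 and nuclear long noncoding RNAs at 89.7. Among other cell types, the stromal list lay at percentile 4.47, B cells at 11.6, endothelial cells at 12.2, mast cells at 22.8, T and NK cells at 26.0 and dendritic cells at 31.6. Neutrophil and erythroid lists lay at 90.1 and 91.6, although their levels were −2.71 and −3.13 in log2(TPM + 0.1). The random lists were drawn from all annotated genes, most of them undetected, and for these 2 lists the median random list stood at −3.32, the level of 0 TPM. A high percentile therefore does not mean that a list was expressed. The mitochondrial, ribosomal protein, housekeeping, small structured RNA and histone lists lay above every random list, and heat shock genes at percentile 98.0.

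Gene levels were correlated between the libraries. Across 14396 detected genes the Pearson correlation of log2 CPM was 0.97, 0.96 and 0.97 for libraries 1 and 2, 1 and 3, and 2 and 3. Genes are not independent replicates, so these values describe the libraries only. Across 12244 genes with a mean of at least 1 TPM the Pearson correlation of log2 TPM was 0.91, 0.87 and 0.89, and Spearman's coefficient 0.93, 0.92 and 0.92, in the same order. The biological coefficient of variation estimated by edgeR was 0.23. Chi-square per degree of freedom between pairs was 43.1, 52.9 and 79.8 against the value of 1 that sampling noise gives. This ratio served only to ask whether 2 samples are the same library, which would lie near 1, and no pair was merged. It says nothing on how separate preparations vary. No gene of 13309 tested had a spread above the trend at an adjusted p of 0.05 by edgeR's quasi-likelihood fit, and 655 had an unadjusted p under 0.05. The trend and prior of that fit were estimated from the same genes. Both numbers therefore set a gene against the other genes and do not measure the spread that genes share. DESeq2 marked 54 genes as dispersion outliers, edgeR without the filter on low counts called 117 of 23976, and leaving out a library gave 17 genes without replicate 1, 49 without replicate 2 and 0 without replicate 3.

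Medians of gene lists nevertheless differed between libraries. Of 45 combinations of 15 lists and 3 libraries, 20 had a median deviation in log2 CPM outside 95% of random lists matched on expression. The random lists hold unrelated genes, so a list whose members vary together can fall outside more often, and the number expected by chance is not known. Deviations are taken from the gene's own mean, so the combinations are not independent. Without replicate 3, 10 of 30 did, and there the deviations of the libraries left mirror each other. Interferon-stimulated genes deviated by 0.40 in library 1, −0.38 in library 2 and −0.14 in library 3. NF-kB genes deviated by 0.32, −0.22 and −0.07, and late inflammatory genes by 0.53, −0.47 and −0.09. Immediate-early genes were instead highest in library 3, with −0.01, −0.28 and 0.26. The matched random lists did not centre on 0, so a sign alone does not place a list against genes of like abundance. For NF-kB genes their medians were 0.10, 0.05 and −0.16, and −0.07 in library 3 lay at percentile 92.6. For immediate-early genes in library 1 the matched median was 0.08, and −0.01 lay at percentile 0.37. The TLR4 pathway list (0.01, 0.04 and −0.05) and the nuclear noncoding list (0.05, −0.07 and 0.07) stayed inside the matched range in each library. Mitochondrial genes deviated by 0.56, 0.00 and −0.47, small structured RNAs (8 entries, with both of Rmrp) by 0.40, 0.23 and −0.84 and ribosomal protein mRNAs by 0.06, 0.23 and −0.27. Macrophage genes deviated by 0.12, 0.13 and −0.24, where the matched medians were 0.07, 0.04 and −0.11, and histone genes by 0.26, 0.10 and −0.38. Genes of dividing cells had −0.20, 0.11 and 0.09, heat shock genes 0.00, −0.21 and 0.15, housekeeping genes −0.04, 0.09 and −0.16, and dendritic-cell genes −0.10, 0.15 and 0.39.

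**Figure D3:**
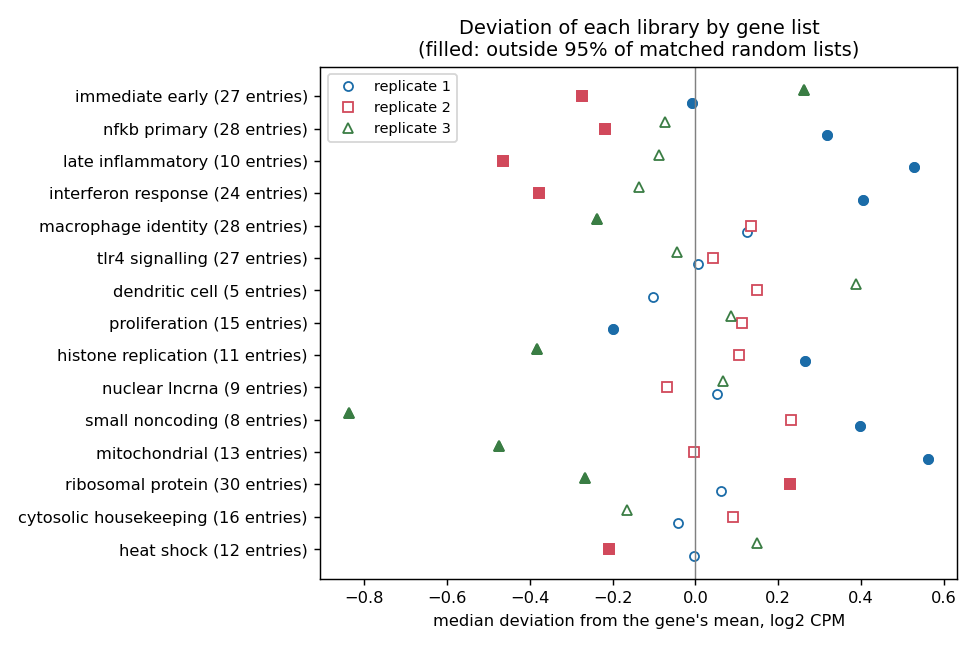
Median deviation of each library from the gene's mean over the 3 libraries, in log2 CPM, for lists with at least 5 detected members. Filled points lie outside 95% of 10000 random lists matched on expression, whose medians can differ from 0. Interferon-stimulated genes reached 0.40 in library 1 and −0.38 in library 2.

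The second quantification was compared gene by gene. Across 12239 genes with a mean of at least 1 TPM, Spearman's coefficient between both quantifications was 0.88 ± 0.02 and Pearson's 0.86 ± 0.03 (SD over 3 libraries), and 2914 genes (23.8%) differed more than 2-fold. The median log2 difference was −0.73, −0.25 and −0.38 in libraries 1 to 3, and with these shifts removed 1671 genes (13.7%) differed more than 2-fold. The largest TPM of the first quantification, those of small nucleolar RNAs, were not kept, with 73442 against 10342 TPM for Gm22988. Among named genes, Tnfaip2 had 1532 TPM in the first and 2637 in the second, Nfkbia 405 and 818, Tnf 274 and 364, Csf1r 202 and 288, and Malat1 16550 and 15208.

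Transcript models that retain introns held a large part of protein-coding expression on chromatin. They took 22.3% ± 1.28 (SD, n = 3) of the expected counts of protein-coding genes with a mean of at least 1 TPM. Protein-coding transcript models took 70.7% ± 1.27 of these counts. In 23.1% ± 0.17 of these genes, models that retain introns held over 50% of the gene's TPM. Among genes with more than 1 transcript model, the main transcript held a median of 48.6% ± 0.14 of TPM. The 5 most abundant protein-coding genes whose main transcript was noncoding in each library were Ifrd1, Lilrb4a, Lilr4b, Sqstm1 and Hnrnpa2b1, and the transcripts named here were annotated as retained introns. Ifrd1-208 held 37.0% ± 1.99 of the gene's TPM, Lilrb4a-206 43.9% ± 3.07, Sqstm1-207 35.1% ± 1.85 and Hnrnpa2b1-208 24.2% ± 2.495. These transcripts are 2303, 1279, 585 and 766 nt long, in the same order. The main transcript is the one with the highest TPM, which divides counts by effective length, so a short model weighs more than in counts. In the second quantification the shares were 21.7% ± 1.48 for Ifrd1-208, 69.4% ± 4.22 for Lilrb4a-206, 38.6% ± 2.97 for Sqstm1-207 and 22.1% ± 1.68 for Hnrnpa2b1-208. Lilr4b, a neighbour and paralog of Lilrb4a on chromosome 10, changed its main transcript between libraries, and Lilr4b-206 held 29.3% ± 3.80, or 34.2% ± 4.24 in the second quantification. Reads of introns absent from any transcript model were not counted in these tables, so the shares are not a measure of all unspliced RNA. Reads of nascent RNA over an annotated intron can fall on these models too, and no other fraction was analysed here. The shares therefore do not separate transcripts that keep an intron from unspliced precursors.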

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

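Entries outside the annotated genes held counts, for phiX and numbered entries in the first quantification and for spike-ins in the second. They were flagged because the total was above 3 counts. Numbered entries and spike-ins are sums over 26248 and 96 entries, for which that limit is no test. No control library was analysed here. The phiX genome, a sequencing control, took 1.03% of expected counts in library 1, 0.244% in library 2 and 0.218% in library 3. The spike-in controls had 0 expected counts in each library but 11, 35 and 47 estimated counts in the second quantification. The entries with bare numbers as names had 35, 27 and 34 expected counts in libraries 1 to 3. No explanation was tested for these values.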

How the results depend on the processing

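TPM rescaled over genes of at least 300 nt was tried only after the data were seen. No contrast changed sign where all 3 libraries had the same sign, and no contrast test could pass 0.05. Numbers of detected genes and of lists above TPM 1 stayed within 1.5 times under each alternative run. The cause of the shifts below was not tested. A pseudocount of 1 gave 6.38 for NF-kB minus late inflammatory genes, 5.82 for immediate-early minus late and 5.35 for macrophage minus other cell types, which a pseudocount of 0.01 put at 10.65. With the second quantification these were 7.35, 5.73 and 7.62, NF-kB minus interferon 3.44, NF-kB minus TLR4 3.56 and nuclear RNA minus ribosomal protein 0.30. With detected members only, NF-kB minus late was 6.99, nuclear RNA minus ribosomal protein 1.19, mitochondrial minus ribosomal protein 1.54 and macrophage minus others 5.91. With means over members, immediate-early minus late was 6.11, NF-kB minus interferon 3.29, nuclear RNA minus ribosomal protein 0.66, mitochondrial minus ribosomal protein 0.13 and macrophage minus others 7.60. Without length correction the last 3 were 1.502, 0.81 and 9.50. Posterior mean TPM gave 1.33 for mitochondrial minus ribosomal protein and 6.36 for macrophage minus others.

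As shares of TPM, nuclear noncoding RNAs took 1.99%, ribosomal proteins 0.042%, protein-coding genes 19.3% and small nucleolar RNAs 48.2%. In counts of the second quantification, nuclear noncoding RNAs took 9.84% and protein-coding genes 59.1%. Over 50% of TPM in retained-intron models was found in 24.4% of genes in the second quantification and 29.4% at a TPM minimum of 10, where the main transcript's median share was 43.0% and 40.7%. Genes with a spread above the trend numbered 117 without the filter, 54 by DESeq2 outliers and 0 to 49 when a replicate was left out. The coefficient of variation was 0.245 without the filter and 0.210 to 0.236 when a replicate was left out. List deviations outside the matched range numbered 10 to 14 when a replicate was left out, where fewer libraries give fewer combinations and the deviations of those left mirror each other. Individual list levels moved by more than their SD for 17 of 22 lists when TPM was rescaled over genes of at least 300 nt and for 16 with the second quantification. No paired analysis was possible because there is 1 group. Depth limits the low genes: Il6, Nos2 and Ifnb1 rest on at most 22 counts in a library.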

Other observations

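The protein-coding genes with the highest mean TPM and the most reads, named here after their values were seen, include several outside the fixed lists. By the mean of 3 libraries, Tnfaip2 was followed by Ifrd1 at 1449 ± 599 TPM (SD, n = 3), which was above it in libraries 2 and 3, the leukocyte receptor genes Lilrb4a at 1269 ± 498 and Lilr4b at 1158 ± 385, and Gpnmb, a lysosomal membrane glycoprotein gene, at 922 ± 273. Next came Sqstm1 (746 ± 133 TPM), Hnrnpa2b1 (744 ± 245), Irf1 (744 ± 193), Ccnl1 (707 ± 177), H2-D1 (684 ± 45.6) and Rbm39 (675 ± 144). By mean share of expected counts, Ahnak was followed by Rnf213 (0.53% ± 0.15), Macf1 (0.52% ± 0.12), Lilr4b (0.42% ± 0.03), Lilrb4a (0.31% ± 0.04), Stab1 (0.30% ± 0.11) and Lrp1 (0.30% ± 0.10). Lilrb4a, Lilr4b and H2-D1 have close paralogs, so their values are uncertain.

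The labels do not give the sex of the mice. Xist stood at 840, 938 and 1242 TPM in libraries 1 to 3. The Y-linked genes Ddx3y and Eif2s3y had 0 expected counts in each library, Kdm5d had 0, 0 and 1 and Uty 1, 1 and 0. In the second quantification Uty had 4.65 ± 2.21 TPM, Kdm5d 3.44 ± 1.47, Ddx3y 0.87 ± 0.44 and Eif2s3y 0.38 ± 0.15, so the 2 quantifications differ for these genes.

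In the patterns that follow, the tests were chosen after the result was seen, except the one for length and GC content. NF-kB and interferon genes were higher in library 1 than in library 2, by a median of 0.62 in log2 CPM over 52 members, and 26 of 28 and 24 of 24 detected members pointed that way. Between the same libraries, late inflammatory genes differed by 1.06 (10 of 10 higher in library 1), mitochondrial genes by 0.57 (9 of 13), immediate-early genes by 0.33 (19 of 27), small structured RNAs by 0.32 (6 of 8 entries, 2 of them Rmrp), ribosomal protein mRNAs by −0.12 (11 of 30) and housekeeping mRNAs by −0.16 (6 of 16). More cytosolic mRNA in library 2 would dilute nuclear noncoding RNAs as well. For 9 of them the median difference was 0.049, with a bootstrap 95% interval over genes of −0.01 to 0.36, and 7 were higher in library 1. Neat1 held 4.25% of expected counts in library 1 and 2.73% in library 2, against 7.43% and 7.29% for Malat1 and 1.32% and 1.25% for Xist. The median argues against more cytosolic mRNA as the whole cause, but members differed and a part in it stays open. The interval covers genes of 1 pair of libraries, not replicates. With lists matched on expression, length and GC content the excess was 0.57, and the highest matched list reached 0.30. The amount of starting RNA and differences between cultures stay open, because each library has its own amount, and no biological explanation was tested.

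The mitochondrial genes mt-Nd3, mt-Co2 and mt-Co3 were at or near 0 in the expected counts. Each of these genes has an annotated nuclear copy of at least 95% identity, on chromosome 1 (Gm28438, Gm28661 and Gm28437). The second quantification gave the lowest of the genes, mt-Nd3, 377 estimated counts over the 3 libraries and its copy Gm28438 0. The first gave mt-Nd3 0 expected counts and Gm28438 303. Reads of this sequence were therefore not lacking. How a tool splits them cannot tell whether they came from the mitochondrial gene, so a scarcity of its own reads was not tested. With the copies added, expected counts were 0.86 of estimated counts, against 0.02 without them and 0.56 to 0.90 for the 9 mitochondrial genes that have no such copy. Reads shared with the nuclear copies may therefore account for the low values, as a hypothesis found and tested on the same data.

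The second quantification assigned 1.51, 1.69 and 1.67 times as many reads as the first in libraries 1 to 3. A factor shared by all genes is argued against as the whole cause. Across 7073 protein-coding genes the log2 ratio was higher by 0.32 (bootstrap 95% interval 0.27 to 0.37) in multi-exon than in single-exon genes, of which there were 58. The median ratio was 1.23 in single-exon and 1.53 in multi-exon genes, so a shared part stays open. Reads that cross borders of exons and introns could add to the excess. The Spearman coefficient with introns per kb of exon was 0.089 (0.065 to 0.111) across genes, which neither supports nor excludes this.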
